A study of Mus musculus with 2 samples.

How the data were processed

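The study measured single-cell RNA in the uterus of wild-type mice on days 4, 5 and 6 of pregnancy, counted from the day of the vaginal plug as day 1. Per the labels' protocols and the design text, tissue was snap-frozen, fixed with formaldehyde and dissociated with a gentleMACS instrument. Libraries were then made with the 10x Genomics Fixed RNA kit and its mouse probe set v1.0.1 and sequenced on an Illumina NovaSeq instrument. In this chemistry a pair of short probes is ligated on each target transcript, and unique molecular identifiers (UMIs) count the ligated pairs. A gene is therefore measured only through its probes, reads carry no information on splicing, and close paralogs can share probes. Per the design text a uterine horn was flushed with saline on day 4, and attachment sites were made visible with a blue dye on day 6. Spatial data from a TAZ knockout named in the design text were not analysed here.

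The deposited values are raw UMI counts per gene and cell, in 6 matrices of 19059 genes. Per the file headers they were made with Cell Ranger 7.1.0, and per the submitters' processing notes on the mm10 genome. The cells in the deposited matrices had been called upstream, and the settings of that call are not given in the sources used here. GEO holds 2 records for the 6 matrices, a record per pooled library. The record of days 4 and 5 holds 4 matrices, and its title names both days with biological replicates 1 and 2 of each. Day and replicate of these 4 matrices were taken from the matrix names, which match that title. Days 4 and 5 thus share a library and day 6 has its own, so any comparison with day 6 is also a comparison of libraries. Comparing day 6 with the 4 pooled matrices, which needs no matrix name, was an alternative. The 2 matrices of each day differed beyond sampling noise, with a chi-square per degree of freedom of 9.57, 27.9 and 9.74 on days 4, 5 and 6, so none was a duplicate.

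Depth per matrix ranged from 21071609 to 41556502 UMIs. Cells with at least 300 detected genes and at most 10% mitochondrial UMIs were kept. They numbered 21825 and 24461 on day 4, 12178 and 11775 on day 5, and 7636 and 11054 on day 6. Doublets were called in each matrix from simulated pairs of cells. The number called was set from the droplet barcodes that the matrices of a library shared. The calls removed 16.1% and 18.4% of cells on day 4, 8.84% and 8.46% on day 5, and 6.02% and 8.88% on day 6. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 40 principal components were taken, and cells were joined to 20 neighbours. Leiden clustering at resolution 1 with seed 1 gave 35 clusters, 3 of them single cells.

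Clusters were named from 169 marker genes fixed before the data were examined, of which 2 were missing from the matrices. A name needed at least 3 detected markers and 33.3% of its list among the genes raised in the cluster. Names are written "X-like" in the methods and shortened in the text, so that stromal cells stand for stromal-like cells. The rule that scored clusters was set after the markers had been seen. A first version compared each cluster with all others and left a cluster of 5509 cells, nearly all of day 4, without a name. The version used compares clusters in 2 passes, and the first version was kept as an alternative. The 33.3% minimum was also set after the markers had been seen. Clusters left unnamed held 1.11%, 4.15% and 0.826% of cells on days 4, 5 and 6.

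Counts were summed per matrix and class, since cells are not replicates, in each class with at least 30 cells in every matrix. This left 9 classes. T-like and mesothelial-like cells fell under the minimum in some matrix. Sums were scaled with TMM, filtered with filterByExpr and tested with edgeR's quasi-likelihood test in a single fit of the 6 sums with day as the factor, which leaves 3 residual degrees of freedom. P-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. They rest on 2 biological replicates per day. An exact permutation test of 2 against 2 matrices cannot give a p under 0.333, so none is reported. Class shares were tested with edgeR on cell numbers, with total cells as library size and no TMM. Whether a day 5 against day 4 change differed between stromal and epithelial cells was tested as the class by day interaction with matrix as a block.

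Before the data were examined, 17 gene lists with 318 genes were fixed, 7 of which were missing from the matrices. They cover decidualization regulators and markers, hedgehog signalling, YAP/TAZ target genes, G1/S and DNA replication, G2/M and mitosis, glycolysis, hypoxia response, matrix genes, steroid hormone response, interferon response, ER chaperones and the unfolded protein response, angiogenic ligands, the prostaglandin pathway, the retinoid pathway, stress and immediate early genes, angiogenic endothelium and uterine NK effectors. The first 15 were tested in stromal cells. The cell cycle, steroid, interferon and stress lists were tested in every other class too, the endothelial list in blood endothelium and the effector list in NK cells. Lists were tested with camera of limma with a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. Fry, of the same package, asked whether members changed in either direction and whether they moved one way on balance, without comparing them with other genes. The lists came from general knowledge and not from these samples.

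The tests, samples, lists, markers and most alternatives were fixed before the data were examined, and so was the rule for genes named in the text. In stromal cells it took the 10 largest rises and the 10 largest falls for days 5 against 4 and 6 against 5, and 5 and 5 for days 6 against 4. Such genes had an adjusted p under 0.05, both matrices of a day above both of the other and a mean of at least 20 CPM, the TMM-scaled unit of edgeR, and were no naming marker. In each list it took up to 4 members with the smallest adjusted p. It took 4 and 4 genes in each other class, and Yap1 and Wwtr1 whatever their test. A gene with a mean CPM at least 5 times higher in another class is named with that fact. Because most genes so named in the other classes had their main source elsewhere, the same rule was also applied to genes whose mean was highest in the class itself, an addition made after the data were seen.

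Levels are given as CPM of the class sum, as mean ± SD with n = 2, and fold changes as log2 values ± standard error. The CPM and log2 values were computed here from the deposited counts. Where a day had no count of a gene, the fold is a lower bound against a floor of 3 counts over the matrices of that day. Where it had 1 to 3 counts, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only. Coordinates are from GENCODE release M21 on GRCm38, which is mm10, counted from 1, and were matched by Ensembl identifier for all 319 named genes. For 12 gene symbols used by more than 1 identifier, each identifier was kept apart.

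The alternatives fixed beforehand were RLE size factors, no TMM, the Wald test of DESeq2, no low-count filter, the replicate number as a block, only the 2 days compared, and each matrix left out in turn. They also included at least 600 genes per cell, doublets kept and clustering at resolutions 0.5 and 2. For stromal cells there were further all cells without class names and thinning to 700 UMIs per cell and 3956 cells per matrix. Thinning left out 3437 and 2407 shallower stromal cells on day 4, 72 and 98 on day 5, and 656 and 691 on day 6. Leaving out a matrix leaves its day with 1 sample, which is then assumed to vary like the other days.

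The steps were tested on simulated data. In simulated stromal sums for day 5 against day 4, edgeR recovered 43.3% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 93.9% of those changed 4-fold, with 3 false calls among 13722 genes. In simulated mural sums it recovered 10.4%, 44.8% and 83.3%, with 2 false calls among 7557 genes. The interaction test recovered 92% of 200 genes changed 4-fold, with 4 false calls among 12186 genes. Camera found 100 of 100 lists raised 1.5-fold with either correlation, and called 1 of 100 unchanged lists with the preset and 0 with the estimated correlation. In the data no stromal list passed with the estimated correlation, so this leaves list calls open. An NK share raised 2-fold was found in 77 of 100 draws, and 31 of 1100 unchanged classes were called.

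Software versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.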

Results

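The data covered 6 single-cell matrices of mouse uterus, with 2 biological replicates on each of days 4, 5 and 6 of pregnancy. The series concerns uterine gene expression during decidualization, in which stromal cells of the endometrium differentiate around the attached embryo. The matrices of day 4 held 21860 and 24472 cells with 27417874 and 35452164 UMIs. Those of day 5 held 12203 and 11809 cells with 34602000 and 25835056 UMIs, and those of day 6 held 7651 and 11058 cells with 21071609 and 41556502 UMIs. The median cell had 1014.5 and 1170 UMIs on day 4, 1820 and 1677 on day 5, and 1382 and 1592 on day 6. Days 4 and 5 were pooled in 1 library and day 6 was in another, so day 6 and its library cannot be told apart in any comparison below. Levels are CPM of the summed class as mean ± SD, n = 2, and changes are log2 values ± standard error. Adjusted p-values of genes and shares are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of lists are from camera unless an estimated correlation is named.

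Stromal cells were the largest class on every day, and natural killer (NK) cells were the class with the largest rise in share from day 4 to day 5 among those with a name. The share of NK cells, the main lymphocytes of the early decidua, was 3.50% ± 0.313 on day 4, 10.8% ± 1.79 on day 5 and 8.04% ± 1.83 on day 6. Stromal cells made up 61.5% ± 0.409, 41.3% ± 1.81 and 63.4% ± 1.22 of cells on days 4, 5 and 6. Epithelial cells made up 14.7% ± 0.193, 17.3% ± 1.66 and 10.6% ± 0.658, and macrophages 3.87% ± 0.576, 6.05% ± 0.578 and 3.88% ± 0.695. From day 4 to day 5 the NK share rose by 1.62 ± 0.239 on the log2 scale (adjusted p = 0.00258), higher in both day 5 matrices than in both of day 4. The stromal share fell by 0.57 ± 0.160 (adjusted p = 0.0428), and the macrophage, dendritic, lymphatic endothelial and mesothelial shares rose by 0.65, 0.78, 0.80 and 0.81 (adjusted p = 0.0428 for each). The unnamed clusters rose by 1.90 (adjusted p = 0.000904). The stromal and unnamed changes depend on a naming rule chosen after the markers had been seen. With the first rule a cluster of 5509 cells, nearly all of day 4, had no name, and the stromal shares of day 4 were 44.9% and 49.8%. The stromal change was then -0.22 (adjusted p = 0.527) and that of the unnamed clusters turned to -1.69. The epithelial, blood endothelial, mural, smooth muscle and T cell shares did not pass the test.

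From day 5 to day 6 the stromal share rose by 0.62 ± 0.160 (adjusted p = 0.0187). At resolution 2, where a day 6 cluster led by immunoglobulin genes had no name, stromal shares of day 6 were 49.6% and 53.2%, and the change of 0.34 did not pass (adjusted p = 0.186). The stromal call also ended with at least 600 genes per cell (0.52, adjusted p = 0.0603) and without any one matrix other than day 5 replicate 2. The epithelial share changed by -0.71 (adjusted p = 0.0174), the smooth muscle share by -0.98 (adjusted p = 0.0204), and the mesothelial share by -1.73 (adjusted p = 0.00618). The lymphatic endothelial share changed by -1.21 (adjusted p = 0.0174), the macrophage share by -0.64 (adjusted p = 0.0436) and the unnamed clusters by -2.34 (adjusted p = 0.000383). The NK share changed by -0.42 (adjusted p = 0.163), which did not pass. Between days 4 and 6 only the NK share passed, higher by 1.20 ± 0.238 on day 6 (adjusted p = 0.025). The NK call on day 5 held with any single matrix left out. The stromal call on day 5 ended without any one matrix of days 4 or 5, with at least 600 genes per cell (-0.42) and with doublets kept (-0.52). With replicate number as a block the 7 calls became 4, those of stroma, macrophages and mesothelium being lost (adjusted p = 0.06 for each). The dendritic and lymphatic calls held without day 4 replicate 1, while the macrophage and mesothelial calls did not, and none of the 4 held without day 4 replicate 2 or either day 5 replicate. The 7 calls of day 5 against day 4 became 4 without day 4 replicate 1 and 2 without day 4 replicate 2, day 5 replicate 1 or day 5 replicate 2. The 7 calls of day 6 against day 5 became 1 without day 5 replicate 1 and 3 without either day 6 replicate. The NK call of day 6 against day 4 ended without day 4 replicate 2. Shares sum to 100%, and over non-stromal cells alone only NK cells (1.01, adjusted p = 0.00861) and the unnamed clusters passed for day 5 against day 4. Macrophage (adjusted p = 0.92), dendritic, lymphatic and mesothelial shares (adjusted p = 0.717 for each) did not pass there, and the macrophage change was -0.07 with TMM over classes. For day 6 against day 5 only the mesothelial share (-1.05, adjusted p = 0.0231) and the unnamed clusters (-1.65) passed over non-stromal cells. The macrophage change was there 0.04, and 0.08 with TMM over classes, the epithelial change was 0.01 with TMM, and that of the unnamed clusters turned to 1.38 at resolution 2. All shares rest on cell names rebuilt here from markers and on tissue that was flushed in a horn on day 4.

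**Figure D1:**
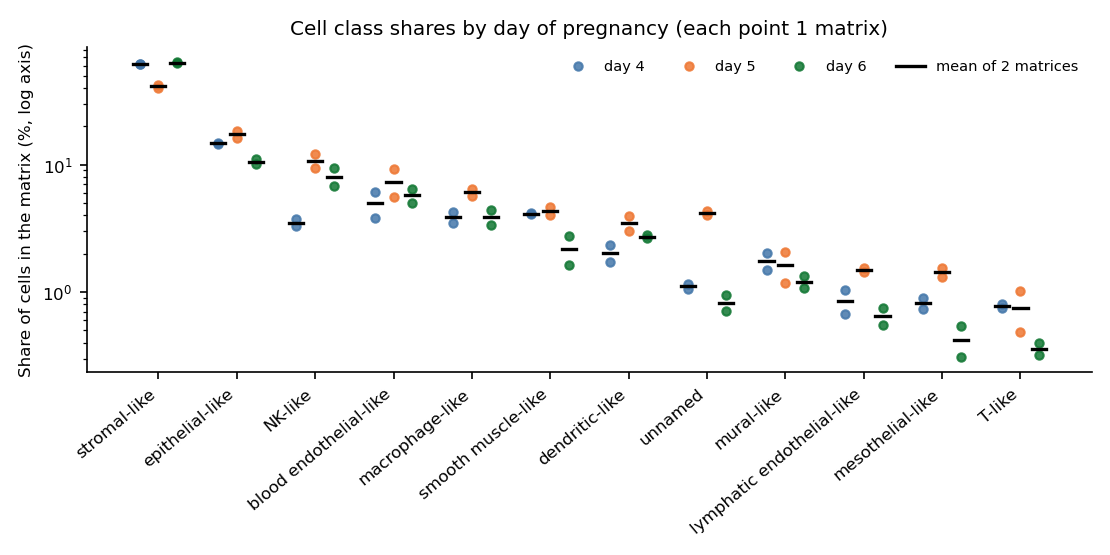
Share of cells in each class by day of pregnancy, in percent on a log axis, with a point for each of the 6 matrices and a bar at the mean of the 2 matrices of a day. NK-like cells rose from 3.50% to 10.8% between days 4 and 5, while stromal-like cells went from 61.5% to 41.3% and back to 63.4% on day 6.

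Stromal cells of both day 5 matrices had higher median UMI counts than those of day 4. Their median UMI count per cell was 1000 ± 56.6 on day 4, 2656 ± 602 on day 5 and 2153.5 ± 306 on day 6. NK cells, with medians of 839, 913.5 and 862, and epithelial cells, with 1154 ± 304, 1574.5 ± 142 and 1056 ± 317, moved less.

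**Figure D2:**
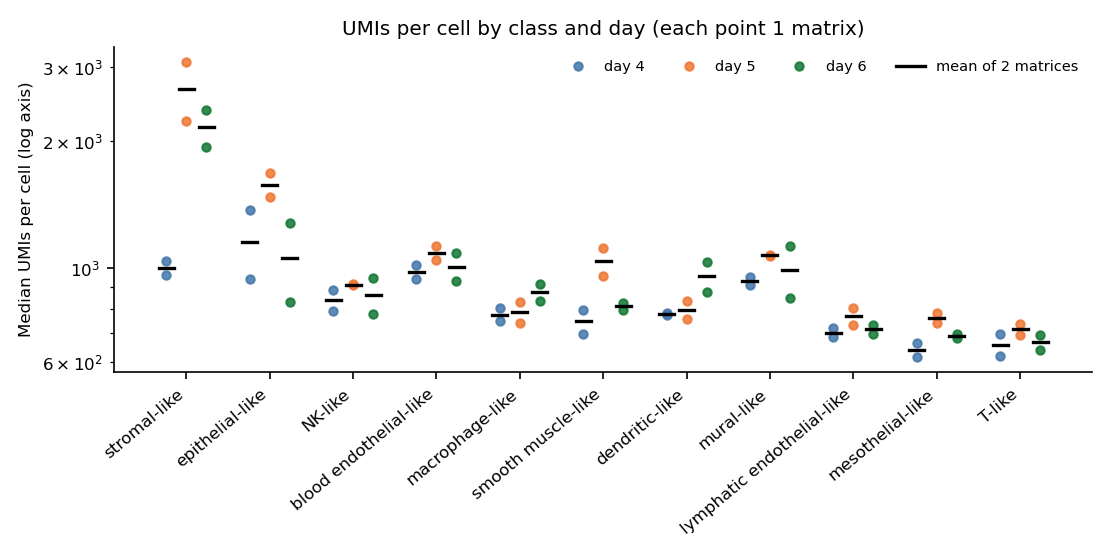
Median UMIs per cell in each class by day of pregnancy, on a log axis, with a point per matrix and a bar at the mean of the 2 matrices of a day. The stromal-like medians of both day 5 matrices lie above those of day 4, with means of 2656 and 1000, whereas NK-like means lie between 839 and 913.5.

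The comparison of day 5 with day 4 in stromal cells asked what changed in the stroma at the start of decidualization. Gja1, the gap junction protein connexin 43, rose from 238 ± 30.3 to 2643 ± 9.15 CPM, a log2 change of 3.47 ± 0.203 (adjusted p = 6.91e-06). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose by 4.91 ± 0.275 (adjusted p = 6.42e-06). Alpl, the tissue-nonspecific alkaline phosphatase used as a decidual marker, rose by 5.36 ± 0.436 from 0.541 to 22.8 ± 11.2 CPM (adjusted p = 2.47e-05). Dio3, the deiodinase that inactivates thyroid hormone, had no count on day 4 and 255 ± 155 CPM on day 5, at least 2500-fold higher. Cyp11a1, which starts steroid hormone synthesis from cholesterol, went from no count to 8.13 ± 5.93 CPM, at least 78.6-fold higher. In all, 6811 of 13722 genes passed the test, 3667 higher and 3144 lower on day 5, and 2812 of them moved by more than 2-fold.

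Other large rises among genes that met the naming rule were those of Sfrp5, a secreted inhibitor of Wnt signalling, with a ratio of 1180 (95% counting interval 211 to 46600), and of Aoc1, a diamine oxidase that breaks down histamine and putrescine, with a ratio of 575 (159 to 4750). Lrat, which esterifies retinol, had a ratio of 230 (78.4 to 1120). Kng1, the precursor of bradykinin, was at least 67.2-fold higher, and Serpinb9b, a member of the serpin family, had a ratio of 115 (20.3 to 4600). Moxd1, a monooxygenase-like protein, rose by 6.33 ± 0.225 to 79.7 ± 14.9 CPM and stood at 21.1 CPM on day 6. Cthrc1, a secreted collagen triple helix protein, rose by 6.07 ± 0.353 to 181 ± 78.6 CPM. Prap1 rose by 6.49 ± 0.725, and its mean level was 176 times higher in epithelial cells. Among genes that met the naming rule, with a mean of at least 20 CPM over the 6 matrices, days that did not overlap and no use as a naming marker, the largest falls were in Kcnc3, a voltage-gated potassium channel, which fell by 4.07 ± 0.213 from 203 ± 42.2 to 12.0 ± 2.94 CPM (adjusted p = 4.87e-06), and in Ryr2, a calcium release channel, which fell by 3.85 ± 0.189. Adarb2, an RNA editing enzyme homologue, changed by -3.60 ± 0.293, Fam155a by -3.21 ± 0.161, Hrk, a pro-apoptotic BH3-only protein, by -2.99 ± 0.218, and Pamr1 by -2.86 ± 0.237. Plekhs1, Slc25a48, Il17rb and Jam2 changed by -3.78, -3.62, -3.38 and -3.00 on the log2 scale, and their mean levels were between 19.8 and 25.7 times higher in epithelial cells. Epithelial markers in stromal cells stood at 6.3% ± 0.1 of their epithelial level on day 4, 1.7% ± 0.3 on day 5 and 5.0% ± 1.2 on day 6.

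Of the lists fixed beforehand, 6 rose on day 5. All 21 measured members of the G2/M and mitosis list rose (adjusted p = 7.4e-43, or 0.161 with an estimated correlation). Among them the cyclin-dependent kinase Cdk1 rose by 2.85 ± 0.131, the ubiquitin-conjugating enzyme Ube2c by 3.10 and the spindle factor Tpx2 by 2.66. In the G1/S and DNA replication list 19 of 22 members rose and 3 did not pass (adjusted p = 2.23e-12, or 0.161 with an estimated correlation). The licensing factor Cdt1 rose by 1.77, the helicase subunit Mcm5 by 1.96 and cyclin E1, Ccne1, by 1.88. ER chaperones and the unfolded protein response had 15 of 18 members higher and none lower (adjusted p = 1.22e-17, or 0.161 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, stood at 169 CPM on day 4 and 922 CPM on day 5, and Manf rose by 2.55 ± 0.138. Among decidualization regulators and markers 15 of 23 rose and 1 fell over all genes, and 16 rose and 1 fell adjusted over the list alone (adjusted p = 7.42e-08, or 0.174 with an estimated correlation). The ligands Bmp2 and Wnt4 rose by 4.40 and 4.23, the small heat shock protein Cryab by 4.71 ± 0.276, and the transcription factor Klf9 fell by 0.65. In glycolysis 12 of 17 rose and 4 fell (adjusted p = 8.39e-05, or 0.161 with an estimated correlation). The glucose transporter Slc2a1 rose by 1.89 ± 0.169 and pyruvate kinase Pkm by 1.44 ± 0.121, while Eno2 and Pfkm changed by -0.85 and -0.81. Matrix genes had 18 of 32 higher and 3 lower (adjusted p = 1.34e-05, or 0.161 with an estimated correlation). Fibulin 1, Fbln1, rose by 2.58 ± 0.173, biglycan, Bgn, from 221 to 930 CPM and the protease inhibitor Timp1 by 2.68. For these lists the count adjusted over the list alone was the same as over all genes except where both are given, and with an estimated correlation no list passed.

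The remaining 9 lists did not pass camera in stromal cells. By fry, which tests whether members change and does not compare them with other genes, each of the 9 passed in either direction (adjusted p = 0.000183 to 0.0203), and angiogenic ligands, prostaglandin and retinoid genes also passed as higher on balance (adjusted p = 0.0031, 0.00441 and 0.00441). In hedgehog signalling 3 of 10 members rose and 2 fell (adjusted p = 0.456), the falls being those of the pathway's own targets Hhip, at -2.81 ± 0.325, and Ptch2, at -1.40 ± 0.197. Retinoid pathway genes had 8 of 15 higher and 3 lower (adjusted p = 0.0629), including the retinol carrier Rbp4 by 2.03 and the retinaldehyde dehydrogenase Aldh1a3 by 4.83, and this list passed without TMM (adjusted p = 0.0383). Angiogenic ligands had 7 of 16 higher and none lower (adjusted p = 0.0629, or 0.0385 without TMM). Ereg, an EGF receptor ligand, was at least 58.8-fold higher among them, and Fgf2 rose by 1.29 and Vegfc by 1.13. Prostaglandin genes had 7 of 15 higher and 4 lower, or 7 and 5 adjusted over the list alone (adjusted p = 0.268), with the prostacyclin receptor Ptgir up by 2.29. Steroid hormone response had 5 of 22 higher and 8 lower (adjusted p = 0.336), including Zbtb16, a progesterone-responsive transcription factor, from 1237 to 507 CPM, and Msx1 and Sox17, which stood 22.0 and 20.4 times higher in epithelial cells. Hypoxia response had 6 of 17 higher and 2 lower (adjusted p = 0.336), with the hypoxia-inducible factor Epas1 up by 2.39. YAP/TAZ target genes had 6 of 20 higher and 7 lower (adjusted p = 0.964), among them Igfbp3, an IGF-binding protein, up by 2.73 and the receptor kinase Axl down by -0.70. Interferon response had 5 of 20 higher and 3 lower (adjusted p = 0.72). Stress and immediate early genes had 6 of 14 higher and 3 lower (adjusted p = 0.471). Their day 5 level rested on 1 of the replicates, as for Ier2 at 256 ± 245 CPM and Junb at 138 ± 121 CPM. The median, mean and test differed in sign for hedgehog signalling (median 0.03, mean -0.28, test down), YAP/TAZ target genes (0.01, 0.30, down) and interferon response (-0.03, 0.06, down).

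Most stromal cells of the different days fell in different clusters. Clusters 0 and 1 held 61.8% and 22.8% of the stromal cells of day 4. Clusters 7, 8 and 10 held 33.2%, 33.9% and 23.3% on day 5, and clusters 4, 6, 15 and 16 held 35.6%, 29.2%, 18.1% and 15.5% on day 6. Cluster 15, with 2162 cells, was named stromal by 8 of 12 markers, but the immunoglobulin genes Igha and Igkc led its raised genes, ahead of Cyp11a1, Bmp2, Tdo2 and Wnt6. At resolution 2 a cluster of 1755 cells led by Igha, Igkc and Igkv4-90 had no name. Cluster 10 was led by cell cycle genes such as Kif23, Ube2c and Cdc20. The 6811 calls became 3865 with thinning, and without TMM 36.1% of the calls were higher on day 5, against 53.8% with it. Removing TMM moved the median log2 change of all genes by -0.200. Against the change of 7 other classes pooled within each matrix, 4025 stromal genes differed, and 3172 of the 6752 calls tested in both (47%) differed there in the same direction. Among genes named above that did not differ there were Ptgs2 (0.98 ± 1.88, adjusted p = 0.738), Sfrp5 (adjusted p = 0.908), Lrat (adjusted p = 0.178), Kng1 and Ereg (adjusted p = 1 for each), Prap1, Slc25a48, Aldh1a3, Rbp4, Ptgir, Fgf2, Vegfc, Axl and Ptch2.

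**Figure D3:**
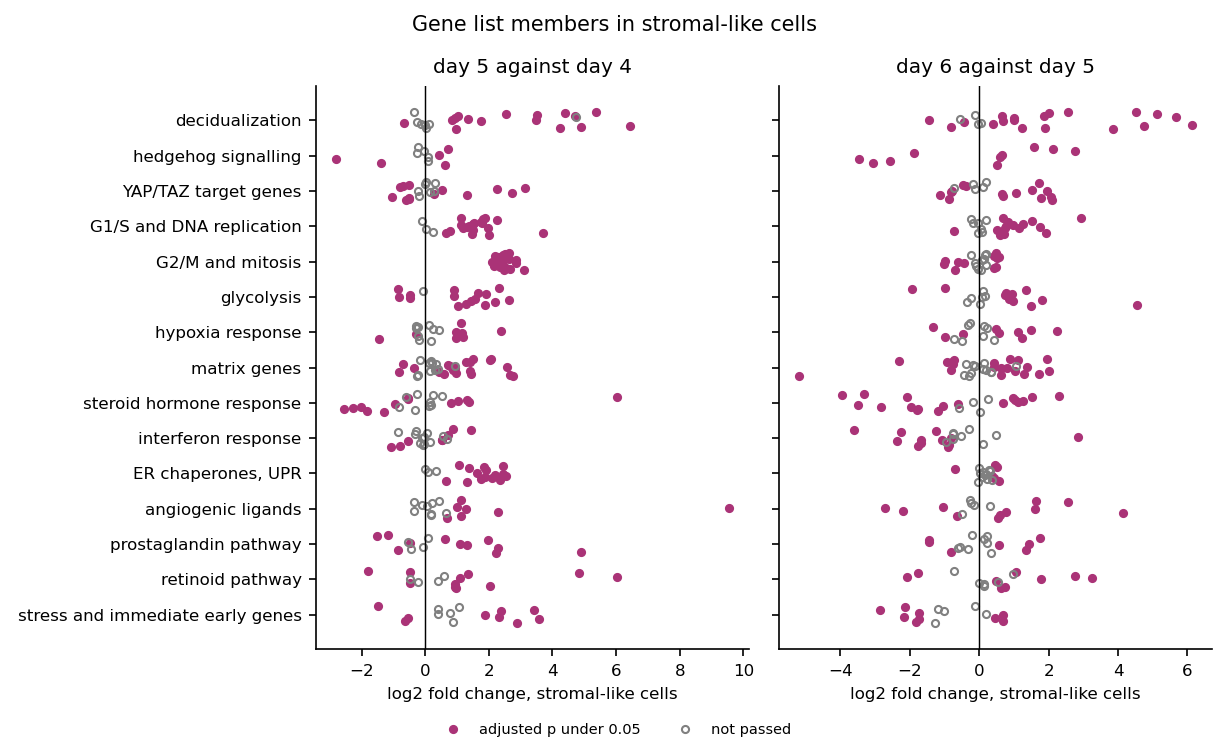
Log2 fold changes of the members of 15 gene lists in stromal-like cells, for day 5 against day 4 and day 6 against day 5. Filled points passed the test (adjusted p under 0.05 by edgeR) and open points did not, and all 21 G2/M genes lie above 0 on day 5, while Ereg, without counts on day 4, is drawn at its fitted value.

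In stromal cells of day 6 against day 5, Wnt6, Alpl and the glucose transporter Slc2a1 rose further. Wnt6, a secreted Wnt ligand, rose from 74.6 ± 1.29 to 1077 ± 7.41 CPM, a log2 change of 3.85 ± 0.207 (adjusted p = 2.69e-06). Slc2a1 rose by 4.55 ± 0.183 from 99.8 ± 2.81 to 2330 ± 376 CPM (adjusted p = 8.86e-07) and Alpl by 4.52 ± 0.287 to 518 ± 24.7 CPM. Hcn4, a pacemaker ion channel, had the largest rise among genes that met the naming rule, by 8.72 ± 0.173 from 0.475 to 204 ± 1.41 CPM (adjusted p = 2.25e-08). Tnc, the matrix glycoprotein tenascin C, had the largest fall among them and decreased by 5.19 ± 0.339 from 131 ± 55.9 to 3.55 CPM (adjusted p = 7.48e-06). In all, 7315 of 13722 genes passed, 3760 higher and 3555 lower on day 6, and 2706 moved by more than 2-fold.

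Further large rises were those of the dopamine receptor Drd4 by 7.02 ± 0.364, the Wnt ligand Wnt10a by 6.64 ± 0.335, the bone morphogenetic protein Bmp6 by 5.15 ± 0.352 and P-cadherin, Cdh3, by 5.56 ± 0.208. The laminin chain Lama1 rose by 5.48 ± 0.181 and the collagen chain Col8a2 by 5.81 ± 0.175 from 6.98 to 395 CPM. Tinagl1, a matrix protein, Nccrp1 and the protease inhibitor Spink8 rose by 6.54, 6.38 and 6.24. Besides Tnc, falls were those of the protease Adamts15 (-3.56 ± 0.198), the Wnt ligand Wnt16 (-3.31 ± 0.199, from 364 ± 18.0 to 36.5 ± 7.62 CPM), the tetraspanin Tspan11 (-3.33 ± 0.124), the NMDA receptor subunit Grin2b (-3.98), Serinc2 (-3.86) and fibulin 7, Fbln7 (-3.26). The laminin chain Lamc3 fell by 3.60 and stood 5.07 times higher in mural cells, and Plekhs1 and Il17rb, with their main source in epithelium, changed by -3.94 and -3.64.

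Among the lists, decidualization regulators and markers had 16 of 23 members higher and 3 lower (adjusted p = 1.06e-05, or 0.642 with an estimated correlation). The coactivator Cited2 rose by 1.86 and angiopoietin 2, Angpt2, by 2.55, while Ptgs2 and the protease Htra1 changed by -0.81 and -1.44. G1/S and DNA replication had 14 of 22 higher and 1 lower (adjusted p = 0.00223, or 0.752 with an estimated correlation), including cyclin D3, Ccnd3, by 2.93 and Mcm4 by 1.76. Glycolysis had 9 of 17 higher and 2 lower (adjusted p = 0.0136, or 0.642 with an estimated correlation), including Tpi1 by 1.48 and Gpi1 by 1.34, while neuronal enolase, Eno2, changed by -1.94. Interferon response fell, with 11 of 20 members lower and 1 higher, or 12 and 1 adjusted over the list alone (adjusted p = 0.00144, or 0.752 with an estimated correlation). Oasl2, an interferon-induced oligoadenylate synthetase-like protein, went from 74.2 to 14.4 CPM and the deubiquitinase Usp18 changed by -1.75, whereas Irf7, a transcription factor of the interferon response, rose by 2.86 ± 0.146.

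Of the 11 lists that did not pass camera, all but stress genes (adjusted p = 0.142) passed fry without regard to direction (adjusted p = 0.000374 to 0.00636), and YAP/TAZ target, angiogenic, prostaglandin and retinoid genes also passed as higher (adjusted p = 0.0286, 0.0286, 0.0444 and 0.0167). Hedgehog signalling did not pass camera, with 6 of 10 members higher and 4 lower (adjusted p = 0.942, median 0.55, mean -0.27, test up). Its 4 falls were all target genes of the pathway, namely Ptch1 from 377 ± 141 to 63.3 CPM, and Ptch2, Gli1 and Hhip, at -3.05 ± 0.217, -1.87 and -3.47 on the log2 scale. The co-receptors Gas1, Boc and Cdon rose by 2.75 ± 0.213, 1.59 and 2.13. YAP/TAZ target genes had 9 of 20 higher and 6 lower (adjusted p = 0.126), among them the growth factor Tgfb2 up by 2.10, Crim1 by 1.52 and Amotl2, which binds YAP, by 1.73. G2/M and mitosis had 6 of 21 higher and 5 lower (adjusted p = 0.694, median 0.09, mean -0.02, test down), with the kinesin Cenpe at -0.99. Matrix genes had 13 of 32 higher and 7 lower, or 14 and 7 adjusted over the list alone (adjusted p = 0.516), including lysyl oxidase, Lox, up by 2.01 and collagen XVIII, Col18a1, at -2.30 ± 0.234. Retinoid pathway genes had 7 of 15 higher and 2 lower, or 8 and 2 over the list alone (adjusted p = 0.127), with the retinoic acid hydroxylase Cyp26b1 up by 3.26 and the binding protein Crabp2 by 2.75. Hypoxia response had 6 of 17 higher and 3 lower (adjusted p = 0.694), steroid hormone response 7 of 22 higher and 11 lower (adjusted p = 0.398), and ER chaperones 6 of 18 higher and 1 lower (adjusted p = 0.501). Angiogenic ligands had 7 of 16 higher and 4 lower (adjusted p = 0.593), with hepatocyte growth factor, Hgf, at -2.20. Prostaglandin genes had 4 of 15 higher and 3 lower (adjusted p = 0.593), with the phospholipase Pla2g4a up by 1.76. Stress genes had 3 of 14 higher and 6 lower, or 3 and 7 over the list alone (adjusted p = 0.501).

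Library and day could not be separated for these values. Against 7 other classes pooled within each matrix, 2251 stromal genes differed, and 1671 of the 7255 calls tested in both (23%) differed in the same direction. This takes out a shift shared by a library's classes but perhaps stromal change too, so a missing call does not tell them apart. Genes named above that were not called there included Hcn4 (1.96 ± 1.11, adjusted p = 0.274), Drd4, Nccrp1, Spink8, Fbln7, Tspan11, Plekhs1 and Ptch2 (-0.87 ± 0.3, adjusted p = 0.0703). The standard errors of Wnt10a (1 ± 1.98), Grin2b (4.45 ± 2.62) and Il17rb (0.01 ± 1.32) were too large to decide. List members not called there were Mcm4, Gpi1, Lox, Crabp2 and Eno2 (0.34, 0.24, 0.50, 1.03 and -0.42, adjusted p = 0.196, 0.178, 0.0762, 0.349 and 0.245). Marker sets of other cell types rose in the stromal sums as well from day 5 to day 6. Luminal epithelial markers went from 32.8 and 45.7 to 405 and 415 CPM, smooth muscle markers from 1241 and 1621 to 3201 and 3638 CPM, and Schwann cell markers from 11.8 and 10.8 to 46.1 and 34.4 CPM. The 7315 calls became 4461 with thinning. Without TMM 32.1% of calls were higher on day 6, against 51.4% with it, and the median log2 change of all genes moved by -0.266.

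**Figure D4:**
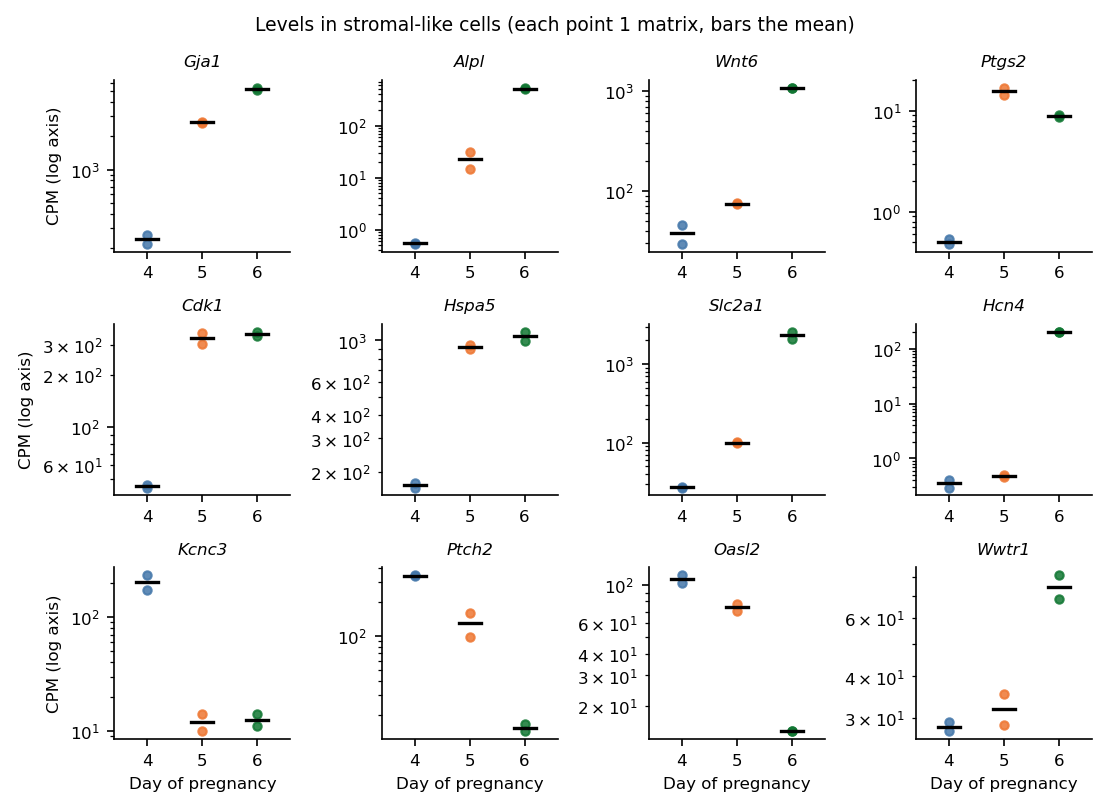
Levels of 12 genes in stromal-like cells in CPM on log axes, against day of pregnancy, with a point per matrix and a bar at the mean of the 2 matrices of a day. Gja1, Alpl, Wnt6 and Slc2a1 were highest on day 6, Ptgs2 on day 5, and Kcnc3, Ptch2 and Oasl2 on day 4.

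Between days 4 and 6 the stroma differed in 9974 of 13722 genes, 5138 higher and 4836 lower on day 6, of which 5685 moved by more than 2-fold. Dio3 was at least 8920-fold higher on day 6, Cyp11a1 at least 2270-fold and Kng1 at least 790-fold. Sfrp5 had a ratio of 44800 (95% counting interval 8050 to 1770000) and Aoc1 a ratio of 6010 (1660 to 49700). The 5 largest falls among genes that met the naming rule were those of Grin2b, at -5.35 ± 0.366, and of 4 genes with their main source in epithelium, which were Plekhs1, Il17rb, Slc25a48 and Lrp2, at -7.71, -7.02, -5.65 and -5.37. Lrp2, the endocytic receptor megalin, stood 25.4 times higher in epithelial cells. Slc2a1 rose by 6.44 ± 0.201 and Alpl by 9.88 ± 0.420 over the 2 days, while Hhip and Ptch2 changed by -6.28 and -4.45.

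Called as higher on day 6 than on day 4 were decidualization regulators and markers, with 18 of 23 members higher and 3 lower (adjusted p = 2.7e-09, or 0.201 with an estimated correlation). So were G1/S, with 20 of 22 higher (adjusted p = 4.45e-10, or 0.201 with an estimated correlation), and G2/M, with 21 of 21 higher (adjusted p = 3.51e-16, or 0.228 with an estimated correlation). Aurora kinase A, Aurka, rose by 3.09 and Cdk1 by 2.94. ER chaperones had 16 of 18 higher and 1 lower (adjusted p = 2.7e-09, or 0.201 with an estimated correlation) and glycolysis 12 of 17 higher and 3 lower (adjusted p = 8.55e-05, or 0.201 with an estimated correlation). Matrix genes had 22 of 32 higher and 6 lower, or 24 and 6 adjusted over the list alone (adjusted p = 0.00264, or 0.256 with an estimated correlation), with Fbln1 up by 3.95. Retinoid pathway genes had 12 of 15 higher and 2 lower (adjusted p = 0.014, or 0.201 with an estimated correlation), with Cyp26b1 up by 4.34. Interferon response was lower, with 11 of 20 members lower and 3 higher (adjusted p = 0.0151, or 0.576 with an estimated correlation). Not passed were hedgehog signalling, with 6 higher and 4 lower (adjusted p = 0.812, median 0.92, mean -0.55, test down), YAP/TAZ target genes, 11 and 6 (adjusted p = 0.24), and hypoxia response, 7 and 3 (adjusted p = 0.392). Nor did steroid hormone response, 9 and 12 (adjusted p = 0.219), angiogenic ligands, 10 and 1 (adjusted p = 0.106), prostaglandin genes, 8 and 4 (adjusted p = 0.219), or stress genes, 2 and 1 (adjusted p = 0.91, median 0.09, mean 0.24, test down), pass. By fry without regard to direction all 15 lists passed (adjusted p = 0.000107 to 0.00109), and of those that did not pass camera YAP/TAZ target, hypoxia, angiogenic and prostaglandin genes passed as higher (adjusted p = 0.00893, 0.0315, 0.000828 and 0.000927). The 9974 calls became 4675 when day 6 was set against all 4 matrices of the other library and 5562 against the pooled other classes. There Sfrp5, Kng1, Aoc1, Grin2b, Plekhs1, Slc25a48, Lrp2 and Hhip did not differ. Without TMM 34.0% of calls were higher, against 51.5% with it, with a shift of the median of -0.446.

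Wwtr1, which encodes the transcriptional coactivator TAZ named in the design, was higher in the stromal sums of day 6 than in those of the other library. Its level was 28.2 ± 1.25 CPM on day 4, 31.9 ± 4.86 on day 5 and 74.9 ± 8.64 on day 6. The change was 0.18 ± 0.146 from day 4 to day 5 (adjusted p = 0.329), 1.23 ± 0.144 from day 5 to day 6 (adjusted p = 0.000174) and 1.41 ± 0.145 between days 4 and 6 (adjusted p = 2.17e-05). Yap1, its paralog, stood at 110 ± 16.2, 141 ± 10.0 and 170 ± 44.3 CPM, and only the difference between days 4 and 6 passed, by 0.63 ± 0.180 (adjusted p = 0.0104). Against the change of the 7 other classes pooled, Wwtr1 was not called from day 5 to day 6 (0.41 ± 0.177, adjusted p = 0.148) or between days 4 and 6 (0.03 ± 0.182, adjusted p = 0.922). A stromal rise was therefore not separated from a shift shared by the classes of the day 6 library. Yap1 still differed between days 4 and 6, by 0.39 ± 0.132 (adjusted p = 0.0333). In the mm10 genome Wwtr1 (ENSMUSG00000027803) spans chromosome 3 from 57455649 to 57575910 on the minus strand, and Yap1 (ENSMUSG00000053110) chromosome 9 from 7931999 to 8004596 on the minus strand. For the other genes that lead the stromal comparisons, the annotation places Gja1 (ENSMUSG00000050953) on chromosome 10 from 56377330 to 56402513 and Dio3 (ENSMUSG00000075707) on chromosome 12 from 110279068 to 110281097. It places Wnt6 (ENSMUSG00000033227) on chromosome 1 from 74771892 to 74785322 and Hcn4 (ENSMUSG00000032338) on chromosome 9 from 58823412 to 58863175. Also placed were Slc2a1 (ENSMUSG00000028645) on chromosome 4 from 119108711 to 119137983 and Kcnc3 (ENSMUSG00000062785) on chromosome 7 from 44590664 to 44604754, all 6 on the plus strand. Alpl (ENSMUSG00000028766), from 137741733 to 137796384, and Tnc (ENSMUSG00000028364), from 63959785 to 64047015, lie on the minus strand of chromosome 4.

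In epithelial cells 2843 genes were called for day 5 against day 4. Numbers of calls also follow the UMIs of a class, so they do not rank the classes by change. Fgg, the gamma chain of fibrinogen, had no count on day 4 and 103 CPM on day 5, at least 249-fold higher, and the serine protease-like Prss35 was at least 263-fold higher. The growth factor Fgf1 fell by 6.58 ± 0.362 from 80.5 to 0.811 CPM (adjusted p = 2.78e-05) and the chloride channel Ano2 fell by 6.39 ± 0.355. From day 5 to day 6, when 2443 genes were called, the kinesin Kif12 was at least 179-fold higher and the anion exchanger Slc4a9 rose by 5.64 ± 0.321 from 4.71 to 227 CPM. Areg, the EGF receptor ligand amphiregulin, was lower by a ratio of 525 (95% counting interval 94.1 to 20800). Prap1 went from 6.28 CPM on day 4 to 2913 ± 1410 on day 5 and 38460 ± 20900 on day 6. Each epithelial cluster was called luminal or glandular by the higher mean of 2 lists of 6 markers. With these names, 2816 genes were called in luminal and 1773 in glandular cells for day 5 against day 4. Guca2b, the peptide uroguanylin, rose by 8.16 ± 0.672 in the latter, and Aqp8, a water channel, rose by 6.73 in luminal cells from day 5 to day 6. Cluster 12, which held most glandular cells of day 4, had no marker of epithelium or its parts among its 10 leading genes, and neither had the luminal clusters 11 and 19. Glandular markers in epithelium stood at 294 and 276 CPM on day 4, 4604 and 3991 on day 5, and 31107 and 17518 on day 6. The steroid hormone response list fell in epithelium from day 5 to day 6, with 6 of 22 members lower and 1 higher, or 7 and 2 adjusted over the list alone (adjusted p = 0.00193, or 0.103 with an estimated correlation). Clusters 11 and 12 held 46.9% and 46.4% of the epithelial cells of day 4, clusters 13 and 21 held 65.1% and 26.2% on day 5, and clusters 19 and 26 held 64.3% and 31.9% on day 6. Of these, 12, 21 and 26 were the glandular ones, so each subclass lay mostly in different clusters on each day. The 2 matrices of day 4 were opposite in this, with 864 cells of cluster 11 and 1709 of cluster 12 in replicate 1 and 1777 and 908 in replicate 2. Changes from day 4 to day 5 in epithelium were not separated from this shift in composition. The epithelial calls were 1260 for day 5 against day 4 without day 5 replicate 1, and 344 for day 6 against day 5 without day 6 replicate 2. In the same 2 settings luminal calls were 1564 and 437, and glandular calls were 904 for day 5 against day 4 without day 4 replicate 1 and 139 for day 6 against day 5 without day 6 replicate 2.

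NK cells gained granzymes on day 5. Gzmd rose by 3.95 ± 0.464 to 377 ± 240 CPM (adjusted p = 4.75e-05), Gzmf by 3.64 ± 0.362 from 52.1 ± 38.1 to 642 ± 121 CPM (adjusted p = 9.15e-06) and Gzme by 3.63 ± 0.520 (adjusted p = 0.000393). These granzymes, cytotoxic serine proteases, lie in one cluster of close paralogs, so probes may not separate them fully and their individual values are uncertain. Of the uterine NK effector list 7 of 15 members rose and none fell, or 9 rose adjusted over the list alone (adjusted p = 9.49e-14, or 0.281 with an estimated correlation). From day 5 to day 6, 7 of the 15 rose, in part the same genes, and 1 fell (adjusted p = 0.0343, or 0.71 with an estimated correlation), and the lectin-like receptors Klrb1b and Klra5 rose by 2.24 and 1.92. The G1/S list fell in NK cells from day 5 to day 6, with 12 of 22 members lower and 2 higher, or 13 and 2 adjusted over the list alone (adjusted p = 0.00368, or 0.196 with an estimated correlation). NK cells had 366 genes called for day 5 against day 4 and 2275 for day 6 against day 5. At resolution 2 the NK class lay in different clusters on days 5 and 6. Cluster 19 there held 63 and 36 cells of day 5 and 428 and 874 of day 6, while clusters 10 and 24 together held most NK cells of day 5 and few of day 6. Changes within NK cells were thus not separated from a change of subset. Dendritic markers in NK cells went from 428 and 384 CPM on day 5 to 663 and 825 CPM on day 6. Stromal markers in NK cells stood at 26.5%, 22.4% and 23.8% of their stromal level on days 4, 5 and 6.

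In blood endothelium Apln, the ligand of the apelin receptor and a marker of sprouting vessels, rose by 4.16 ± 0.211 from 36.3 ± 14.3 to 668 ± 5.81 CPM between days 5 and 6 (adjusted p = 3.46e-09). Hapln1, a hyaluronan link protein, rose by 3.73 ± 0.325, and Vwf, von Willebrand factor, fell by 2.43 ± 0.195 from 330 to 59.8 CPM (adjusted p = 4.99e-07). Rasal1, a Ras GTPase-activating protein, rose by 1.83 ± 0.244 on day 5 and fell by 2.83 ± 0.288 on day 6. The angiogenic endothelium list had 3 of 16 members higher and none lower on day 5, or 7 higher adjusted over the list alone (adjusted p = 1.89e-06, or 0.345 with an estimated correlation). From day 5 to day 6 it had 10 higher and none lower, or 11 over the list alone (adjusted p = 9.73e-07, or 0.285 with an estimated correlation). Between days 4 and 6 it had 13 higher (adjusted p = 1.36e-09, or 0.293 with an estimated correlation). Calls numbered 192 for day 5 against day 4 and 3811 for day 6 against day 5. At resolution 2 a cluster of 333 endothelial cells, with Apln, Aplnr and the mural marker Rgs5 among its leading genes, held 128 and 154 cells of day 6, against 19 and 20 of day 5. Its cells had 2.29 times the median UMIs of their matrix, so a subset was not excluded as the carrier of the pooled change. Mural markers in these sums rose alongside, from 530 and 565 CPM on day 4 to 848 and 704 on day 5 and 2243 and 2550 on day 6, while endothelial markers stayed between 9274 and 10295 CPM. Stromal markers stood at 18.0%, 17.8% and 15.8% of their stromal level in these cells.

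In macrophages the iron exporter Slc40a1 rose by 3.97 ± 0.361 from 20.7 to 339 CPM between days 5 and 6, heme oxygenase, Hmox1, by 3.01 ± 0.223 from 121 to 978 CPM, and platelet factor 4, Pf4, by 2.95 ± 0.226, while complement C4b fell by 2.09 ± 0.296. At resolution 2 a cluster with Pf4 among its leading genes held 42 and 130 macrophages of day 6, against 12 and 5 of day 5. Its cells had 1.25 times the median UMIs of their matrix, so a subset was not excluded as the carrier of the rises. On day 5 the lectin Fcna had risen by 3.61 ± 0.528 to 199 ± 177 CPM. In macrophages 19 of 21 G2/M members rose on day 5 (adjusted p = 6.32e-27, or 0.117 with an estimated correlation) and 16 from day 5 to day 6, or 17 over the list alone (adjusted p = 9.42e-12, or 0.231 with an estimated correlation). Calls numbered 603 and 1869 in these comparisons. Neutrophil markers in macrophages stood at 452 and 436 CPM on day 4, 319 and 219 on day 5 and 150 and 176 on day 6, and lymphatic markers at 23.0 and 35.1, 106 and 316, and 242 and 178 CPM. Stromal markers stood at 27.8%, 30.6% and 22.4% of their stromal level. In smooth muscle the peptides Npy and Nppa were at least 32.7-fold and 22.4-fold higher on day 5, and Igfbp2, an IGF-binding protein, rose by a further 5.02 ± 0.279 to 1994 CPM on day 6. Thbs4, a matrix thrombospondin, rose by 3.84 ± 0.277 on day 6. Smooth muscle had 903 and 789 calls, which became 314 without day 4 replicate 1 and 228 without day 6 replicate 2, with stromal markers at 48.8%, 43.9% and 52.4% of their stromal level. In its G2/M list 15 of 21 rose on day 5, or 17 over the list alone (adjusted p = 2.8e-14, or 0.103 with an estimated correlation). From day 5 to day 6, 12 of the 21 rose, or 16 over the list alone (adjusted p = 2.83e-13, or 0.111 with an estimated correlation). Between days 4 and 6 all 21 rose, and this list passed with the preset and estimated correlation (adjusted p = 4.05e-22 and 0.027).

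Mural, dendritic and lymphatic endothelial cells had 82, 145 and 231 for day 5 against day 4 and 445, 1202 and 49 calls for day 6 against day 5. In mural cells the immediate early factor Egr1 rose by 3.58 on day 5, Dlk1, a Notch-family ligand, by 2.46, and Nrip2 and Tspan17 changed by -3.19 and -2.86 on day 6. In dendritic cells the aspartic protease Napsa fell by 1.97 ± 0.245 on day 5, and the calcium-binding protein S100a4 rose by 3.09 ± 0.262 from 102 to 884 CPM on day 6. The dendritic class itself shifted, as cluster 20 held 44.4% of it on day 5 and 65.7% on day 6. Its dendritic markers went from 4210 and 4039 CPM to 2182 and 2692 CPM and its macrophage markers from 1557 and 1091 to 2305 and 2377 CPM, so these changes were not separated from its make-up. In lymphatic endothelium thrombospondin 1, Thbs1, rose by 2.41 ± 0.375 and Col23a1 fell by 2.51 on day 5, and the connexin Gjc2 rose by 2.11 on day 6. Stromal markers stood at 60.2%, 45.8% and 37.3% of their stromal level in mural cells, 28.2%, 31.7% and 22.2% in dendritic cells, and 55.1%, 36.1% and 29.3% in lymphatic endothelium. For day 5 against day 4 the mural calls became 58 without day 4 replicate 2, and the dendritic and lymphatic calls 49 and 63 without day 4 replicate 1. For day 6 against day 5 the mural and dendritic calls became 70 and 413 without day 6 replicate 2, and the lymphatic calls 31 without day 6 replicate 1.

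The cell cycle, steroid hormone, interferon and stress lists were tested in every class outside the stroma. In what follows the first adjusted p of a pair is from camera with its preset correlation and the second with an estimated one. Directions are those of the preset test, and no list of this and the next paragraph passed with an estimated correlation. For day 5 against day 4, G2/M rose in epithelium with 13 of 21 members higher, or 15 over the list alone (adjusted p = 4.16e-05, or 0.475), and in lymphatic endothelium with 3 of 9, or 7 over the list alone (adjusted p = 8.37e-06, or 0.128). In dendritic cells the preset test passed although 0 of 21 members were called, or 5 over the list alone (adjusted p = 1.05e-05, or 0.484), and in NK cells G2/M fell with 2 of 21 lower (adjusted p = 1.93e-05, or 0.281). G1/S rose in macrophages with 6 of 21 higher, or 10 over the list alone (adjusted p = 1.96e-10, or 0.117), in smooth muscle with 9 of 18, or 14 over the list alone (adjusted p = 1.81e-08, or 0.19), and in lymphatic endothelium with 6 of 11, or 7 over the list alone (adjusted p = 4.45e-08, or 0.0661). Stress genes rose in mural cells with 5 of 10, or 8 over the list alone (adjusted p = 3.84e-14, or 0.223) and in smooth muscle with 9 of 13, or 11 over the list alone (adjusted p = 3.33e-08, or 0.103). They also rose in blood endothelium with 3 of 12, or 6 over the list alone (adjusted p = 1.02e-06, or 0.142) and in epithelium with 4 of 13, or 7 over the list alone (adjusted p = 0.0291, or 0.475). They rose further in lymphatic endothelium with 2 of 8, or 5 over the list alone (adjusted p = 0.00953, or 0.128) and in NK cells with 1 of 10, or 5 up and 1 down over the list alone (adjusted p = 0.0313, or 0.383). Interferon response rose in epithelium with 7 of 19, or 8 over the list alone (adjusted p = 0.0258, or 0.616). Steroid hormone response fell in lymphatic endothelium with 2 of 10 lower and 1 higher, or 5 and 1 over the list alone (adjusted p = 0.0183, or 0.128).

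For day 6 against day 5, G1/S rose in epithelium with 15 of 22 higher, or 18 over the list alone (adjusted p = 9.63e-12, or 0.0517) and in blood endothelium with 13 of 22 higher and 2 lower (adjusted p = 9.73e-07, or 0.285). It also rose in macrophages with 13 of 21 (adjusted p = 7.55e-10, or 0.231), in dendritic cells with 10 of 19, or 13 over the list alone (adjusted p = 2.04e-06, or 0.269) and in mural cells with 7 of 18, or 8 over the list alone (adjusted p = 5.44e-06, or 0.191). G2/M rose in epithelium with 14 of 21, or 16 over the list alone (adjusted p = 7.37e-10, or 0.145) and in dendritic cells with 5 of 21, or 6 over the list alone (adjusted p = 0.00136, or 0.319), as well as in mural cells with 5, or 6 over the list alone (adjusted p = 2.06e-05, or 0.191). In lymphatic endothelium 0 of 9 members were called, or 1 over the list alone, though the preset test passed (adjusted p = 0.00458, or 0.4). Interferon response fell in epithelium with 9 of 19 lower and 1 higher (adjusted p = 0.000636, or 0.455) and in blood endothelium with 8 of 17 lower and 1 higher, or 8 and 3 over the list alone (adjusted p = 0.0147, or 0.601). It also fell in macrophages with 5 of 17 lower and 1 higher (adjusted p = 0.0221, or 0.26) and in mural cells with 3 of 11 lower, or 4 over the list alone (adjusted p = 0.000209, or 0.191). Stress genes fell in lymphatic endothelium with 1 of 8 lower (adjusted p = 0.0419, or 0.4). Between days 4 and 6 the NK effector list had 11 members higher and 1 lower (adjusted p = 3.52e-09, or 0.321). The lists of these classes not named for a comparison of neighbouring days did not pass in it.

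Over the 8 classes outside the stroma, 5365 calls were made for day 5 against day 4, 12883 for day 6 against day 5 and 22760 for day 6 against day 4. When only genes with their highest mean in the class tested were counted, 1420, 2271 and 3783 remained. Of the 8 genes named by size of change for day 5 against day 4, 5 had their main source elsewhere in NK cells, 7 in blood endothelium, 7 in macrophages and 0 in epithelium. The 12883 calls became 5935 with DESeq2. The 5365 calls became 3163 with DESeq2. With TMM 7451 calls of day 6 against day 5 were higher and 5432 lower, and without it 6134 and 7378. For day 6 against day 4 the split was 12719 and 10041 with TMM and 10590 and 13598 without it.

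Stromal and epithelial cells differed in their change from day 4 to day 5. The interaction test called 3340 of 13871 genes, 1379 with a higher and 1961 with a lower change in stroma. Among 12186 genes tested in both classes 3283 differed, and 207 of these were called in opposite directions. Without day 5 replicate 1 the count was 1895 and without day 5 replicate 2 it was 2161.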

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

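The tests of free RNA, of the day 6 library and of sequencing depth, and the comparison with other classes pooled, were chosen after the results had been seen, while those of doublets, shallow barcodes and cycling cells had been written before. Stromal and epithelial cells differed in their change from day 4 to day 5 in 3340 genes by the interaction test, and 10 of these were among the 20 stromal genes named by size of change. Cthrc1 rose more in stroma, with a difference of 2.80 on the log2 scale, stromal minus epithelial. Cyp11a1 and Aoc1 had fitted differences of 7.53 and 7.43, which depend on the prior count because stroma had no count and 0.0591 CPM of them on day 4. Kcnc3, a potassium channel, had a difference of -2.47 and Pamr1 of -1.66. Plekhs1, Slc25a48, Il17rb, Jam2 and Prap1, which all stood many times higher in epithelium, had differences of -1.60, -1.28, -1.48, -1.29 and -2.50. These differences were not separated from free epithelial RNA in the stromal sums. Epithelial markers there went from 6.3% ± 0.1 of their epithelial level on day 4 to 1.7% ± 0.3 on day 5, while UMIs per stromal cell rose 2.66-fold. Genes named from the lists differed too, among them Alpl (4.49), Ptgs2 (4.02), Gja1 (1.28), Ube2c (1.86), Tpx2 (1.36) and Igfbp3 (-4.08).

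Genes with their main source in stroma or epithelium were called as changed in other classes, and 846 of 885 such calls went in the direction of the source. Doublets with stromal cells were argued against as the only source of stromal marker UMIs in NK cells, macrophages and blood endothelium. These UMIs were in 5.15 times as many cells as doublets would need (2.66 to 10.18 over matrices and classes), and in 89.38% to 100% of cells. Free RNA of stroma and epithelium in every droplet stayed open, alone or with doublets. Over all 885 calls, the median log2 difference between the change in a class and its source was 0.835. That pooled value is too large for a plain copy and too small to exclude one. From day 5 to day 6, genes of stromal source differed by 0.34 in NK cells to 0.532 in macrophages, closer to a copy. They stood at 15.1% to 18.7% of their stromal level. From day 4 to day 5 they differed by 0.586 to 1.669, leaving out lymphatic endothelium with 1 gene. Genes of epithelial source differed by 0.584 to 1.343 where a class had more than 1. A change of these genes within the other classes stays open too, untested.

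On day 6 against day 5, 16 of 3744 genes at like levels in all classes moved by over 2-fold the same way in all 9 classes, all 16 higher, against 0 on day 5 against day 4. They included cyclin D3, Ccnd3, with a median change of 2.57 over the classes, the glycolytic enzyme Aldoa (2.18), the elongation factor Eef1a1 (1.87) and the actin Actg1 (1.85). A difference between the day 6 library and the other library cannot be told apart from the day itself, since no day was in both libraries. Free stromal RNA stayed open as well, because over 283 such genes called in stroma the other classes changed by a median of 0.665 of the stromal change (quartiles 0.474 to 0.815). A biological change of day 6 common to all classes remains untested.

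UMIs per stromal cell rose 2.66-fold from day 4 to day 5. Deeper sequencing of the day 5 matrices was argued against, since the other classes rose by a median of 1.10-fold (1.02 to 1.39). More shallow barcodes called as cells on day 4 were argued against as the whole cause, because the 90th percentile of UMIs per stromal cell also rose, 3.26-fold. Stromal cells without any cell cycle UMI rose 1.52-fold, over 274 cells of day 5 and 6855 of day 4. That ratio does not decide whether more cycling cells explain the rise, because cells without such a UMI are selected for few UMIs, with medians of 1128.5 and 1312.5 on day 5 against 3082 and 2230 in the whole class. More cycling cells on day 5 stayed open. A larger RNA content of stromal cells on day 5 stays a hypothesis.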

How the results depend on the processing

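The first rule for naming clusters, the comparison with other classes pooled, and the counts without genes that have their source elsewhere were chosen after the data had been seen, and the other alternatives were planned. Of 9836 comparisons of 629 named results with their alternatives, 9459 kept direction and side of the threshold. Of the rest, 357 lost and 13 gained the threshold and 7 changed direction, and 458 results were kept in every alternative counted. This tally leaves out settings that gave a gene no adjusted p, the counts without genes that have their source elsewhere, and the comparison with other classes pooled. In that last comparison 47% of stromal calls for day 5 against day 4 and 23% for day 6 against day 5 differed in the same direction. Most named genes had also been chosen for large changes that passed the test. The cause of each change below was not tested, except that thinning and leaving out matrices give fewer counts or samples by construction. Depth limited the smaller classes, and with 2 matrices per day every p rests on 3 residual degrees of freedom. Same-numbered replicates of different days did not deviate together, with correlations of -0.058 for days 4 and 5, 0.186 for days 4 and 6 and -0.315 for days 5 and 6 over 9048 genes, so the numbers do not pair the matrices.

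Stromal calls for day 5 against day 4 (6811) were 3865 with thinning, 4025 against the other classes pooled and 4365 to 6925 with a matrix left out, lowest without day 4 replicate 1. Those for day 6 against day 5 (7315) were 4461, 2251 and 4330 to 7498, lowest without day 6 replicate 2. Those for day 6 against day 4 (9974) were 4675 with day 6 against the 4 matrices of the other library, 5562 against the other classes pooled and 8269 to 10574 with a matrix left out. With replicate number as a block the stromal counts were 6284, 6901 and 9732, with DESeq2 6243, 6862 and 9554, and with the first naming rule 6685, 7269 and 9818.

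In the other classes the 5365, 12883 and 22760 calls became 3163, 5935 and 12936 with DESeq2 and 1420, 2271 and 3783 over genes highest in the class tested, and the first became 8786 with doublets kept. With a matrix left out they were 3073 to 5024, 3485 to 13596 and 10826 to 23318. The lowest and highest counts over planned settings, for days 5 against 4, 6 against 5 and 6 against 4, were as follows. NK cells had 102 (without day 4 replicate 1) to 1523 (doublets kept), 430 (without day 6 replicate 2) to 3854 and 1166 to 5330. Blood endothelium had 110 (DESeq2) to 478 (no filter), 1738 to 4136 and 2641 to 5202, and dendritic cells 44 to 446, 290 to 2811 and 609 to 4087 (lowest with DESeq2, highest with doublets kept). Epithelium had 1260 to 3803, 344 to 3433 and 2874 to 6464, luminal cells 1564 to 3543, 437 to 3311 and 2507 to 5656, and glandular cells 904 to 2274, 139 to 2415 and 1943 to 5365. Lymphatic endothelium had 57 to 465, 21 to 85 and 184 to 544, macrophages 164 to 1148, 213 to 2073 and 1431 to 4166, mural cells 35 to 146, 70 to 575 and 325 to 1317, and smooth muscle 192 to 1329, 227 to 910 and 997 to 2629. The interaction count of 3340 was 1895 to 3214 with a matrix left out, lowest without day 5 replicate 1 and 2161 without day 5 replicate 2.

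Of the 12 class shares, the 7 called for day 5 against day 4 were 4 with a replicate block, 3 with TMM over classes, 2 over non-stromal cells, 2 to 7 with a matrix left out, 3 with at least 600 genes per cell and 2 with doublets kept. The 7 called for day 6 against day 5 were 2 with TMM, 2 over non-stromal cells and 1 to 6 with a matrix left out. The 1 called for day 6 against day 4 was 2 with the block, 4 over non-stromal cells, 0 to 3 with a matrix left out, 4 with 600 genes, 6 with doublets kept, 2 and 5 at resolutions 0.5 and 2, and 5 with the first naming rule. The stromal change of -0.57 on day 5 lost its call with the block (-0.57), 600 genes (-0.42), doublets kept (-0.52), the first naming rule (-0.22) and without any matrix of days 4 or 5 (-0.62 to -0.53 over all 6 matrices). That of 0.62 on day 6 against day 5 lost it with 600 genes (0.52), resolution 2 (0.34) and without any matrix but day 5 replicate 2 (0.57 to 0.64 over all 6). The NK change of 1.20 for day 6 against day 4 was 0.95 to 1.42 with a matrix left out and lost its call without day 4 replicate 2 (1.11).

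Share changes that turned direction were, for day 5 against day 4, T cells (-0.70 to 0.39 with a matrix left out, turned without day 4 replicate 2, 0.00, and day 5 replicate 2, and 0.02 with 600 genes), blood endothelium (-0.12 with TMM, -0.03 over non-stromal cells), epithelium (-0.49 and -0.38 likewise), and macrophages (-0.07 with TMM). Others that turned were mural cells (0.12 without day 4 replicate 2, 0.23 without day 5 replicate 1), smooth muscle (-0.64 with TMM, -0.54 over non-stromal cells, -0.03 to 0.16 with a matrix left out, turned without day 5 replicate 2) and the unnamed clusters (-1.69 with the first naming rule). For day 6 against day 5 they were NK cells (0.31 with TMM, 0.26 over non-stromal cells), blood endothelium (0.32, 0.32, and -0.68 to 0.05 with a matrix left out, turned without day 5 replicate 2), dendritic cells (0.37, 0.33), epithelium (0.01 with TMM), macrophages (0.08, 0.04), mural cells (0.26, 0.25, and -0.78 to 0.02 likewise) and the unnamed clusters (1.38 at resolution 2). For day 6 against day 4 they were blood endothelium (-0.09 to 0.59 with a matrix left out, turned without day 4 replicate 1), macrophages (-0.14 without day 4 replicate 2, -0.19 to 0.18 over all left-out matrices, lowest without day 6 replicate 2, -0.29 with doublets kept), stroma (-0.26 at resolution 2) and the unnamed clusters (3.49 at resolution 2).

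The stromal lists called, 6, 4 and 8 in the 3 comparisons, were 7, 4 and 8 with the block, 8, 4 and 8 without TMM and 0, 0 and 0 with an estimated correlation, where the lowest adjusted p was 0.161, 0.642 and 0.201. The block added the retinoid pathway for day 5 against day 4 (adjusted p = 0.0424). Lists that turned direction were YAP/TAZ target genes for day 5 against day 4 with the block (adjusted p = 0.920), hedgehog signalling for day 6 against day 5 with the block (adjusted p = 0.974) and stress genes for day 6 against day 4 without TMM (adjusted p = 0.670). Genes that turned were Retnla in macrophages for day 6 against day 5 with doublets kept (0.66), and in stroma Rdh10 for day 5 against day 4 over all cells (-0.08), and Wwtr1 for day 5 against day 4 without TMM (-0.02) and without day 5 replicate 1 (-0.00). Others were, in stroma, Junb for day 6 against the 4 pooled matrices (-0.86), Ptgs1 for day 6 against day 5 over all cells (-0.40) and Yap1 for day 6 against day 5 without day 6 replicate 2 (-0.03 to 0.51 over the left-out matrices).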

Other observations

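The tests below are those of the report, and no further test was chosen after the results were seen. Besides the classes compared, a cluster of 102 cells without a name, 99 of them of day 6, was led by the prolactin family genes Prl3c1 and Prl8a2, Plekhg4, the plasminogen activator inhibitor Serpine1, Aoc1 and Cyp11a1. Another unnamed cluster, of 1365 cells, was led by Retnlg and the chemokine receptor Ccr3. It held 420 cells of day 4, 905 of day 5 and 40 of day 6. Neither had enough fixed markers for a name, and only their joint share was tested.

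Within epithelium, glandular and luminal cells each had genes that rose from few or no counts. In glands the fibrinogen chain Fga was at least 35.5-fold higher on day 5 than on day 4, and Obp2a, a lipocalin, rose by 4.10 ± 0.244 from 23.2 to 392 CPM from day 5 to day 6. In luminal cells Atp13a4, a cation-transporting ATPase, was at least 274-fold higher on day 5, and Depp1 had a ratio of 4700 (95% counting interval 844 to 186000). In epithelium as a whole Ptgdr, a prostaglandin D receptor, was at least 587-fold higher on day 6 than on day 4 and Fam83a was at least 225-fold lower, and the somatostatin receptor Sstr4 fell by 4.78 from day 5 to day 6. In macrophages Plau, the urokinase-type plasminogen activator, stood at 141, 357 and 1476 CPM on days 4, 5 and 6, higher by 3.39 ± 0.263 on day 6 than on day 4.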
